A study of Rattus norvegicus with 24 samples.

How the data were processed

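Female rats aged 6 months were ovariectomised or sham operated, and hippocampal RNA was sequenced in 24 libraries of 4 groups; groups and replicate numbers were taken from the labels. Per the labels, RNA was extracted with TRIzol and PureLink columns with DNase treatment, and libraries followed Illumina protocols. The submitters' notes name kallisto 0.43 for quantification and DESeq2, without a version, for normalisation; the genome build and annotation behind the values, filters and sequencing batches are not given in the sources used here. The deposited file holds normalised counts, a signal in arbitrary units per gene and library that the authors made. Its values were checked: they are not whole, none is negative, upper quartiles over tested genes ran from 2028 to 2088, and column totals ran from 35.4 to 38.8 M (mega). Whole reads could not be recovered for most genes. Depth was estimated as the column total divided by the smallest step of a library, the value of 1 read, since values at 2 reads were 1.99 to 2.01 times this step; estimated reads ran from 26.5 to 53.6 M per library. Intervals from counting were not computed, as read counts are not given, so precision rests on the spread between libraries.

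Of 20318 features, 2378 had no gene symbol (954 of those tested), and 205 fell into 80 sets with identical values (33 tested); 77.3% of the symbols matched the reference. Values were analysed as log2(normalised count + 1) in R 4.3.3 with limma 3.58.1. Genes with a mean normalised count of at least 10 over all libraries were tested, 16119 in number. All 24 libraries went into 1 fit with a mean per group, the empirical Bayes step with a mean-variance trend, 6 contrasts, and Benjamini-Hochberg adjustment with a threshold of 0.05. Gene lists were tested against all other genes with limma's camera at a preset correlation between genes of 0.01, adjusted over the 34 lists, each with at least 5 tested members, and again with the correlation estimated per list. For each list the number of members passing when adjusted over the list alone was counted. Of 204 pairs of list and comparison, 20 had a median, mean and test that differed in sign, and 0 of these passed. Pearson correlations of fold changes across genes were set beside 200 simulations with unchanged groups and beside divisions of the OVX libraries between the comparisons. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.

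The groups, comparisons, tests, thresholds, gene lists, the rule for naming genes and most alternatives were fixed before the data were examined. The rule named, per comparison, the 8 largest rises and 8 largest falls among passing genes with a mean of at least 50 and a symbol, or the 5 smallest p where fewer than 5 passed. It added up to 4 members with the smallest p of each list that passed or held a passing gene, and Esr1, Esr2, Gper1, Pgr, Gfap, Aif1, Cd74, C3, Bdnf and Ttr. The text gives those among them whose function is best known, picked after their values were seen. The alternatives fixed in advance were a pseudocount of 0.5 or 8, no filter or a mean of at least 100, quantile normalisation, upper quartile rescaling, fitting each pair of groups alone, a robust empirical Bayes step, library weights, the replicate number as a block, the choroid plexus score as a covariate, an estimated correlation between genes, leaving out each library, and dividing the OVX libraries. Chosen after seeing the data were the library set as a term, the set with the choroid score, fits within the low or the high set, and permutation tests of list scores, which were exact over all assignments of libraries and two-sided. Linear models of list scores with a covariate or within the low set, also chosen then, gave the changes with SE in the closing section. Under quantile normalisation and upper quartile rescaling no list that had passed changed direction, and the median change of all genes lay between -0.0123 and 0.00970 on the log2 scale. Other splits of the libraries were drawn 100 times with a fixed seed.

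The lists covered estrogen receptors and steroid enzymes, estrogen-responsive genes, microglia, complement, MHC class I and class II, interferon response, cytokines, leukocytes, mitochondrial and nuclear respiratory genes, glycolysis, fatty acid oxidation, cholesterol, myelin, oligodendrocyte precursors, astrocytes, endothelial and mural cells, fibroblasts, choroid plexus, blood, dentate gyrus, CA1, CA2 and CA3, neighbouring regions, glutamatergic and GABAergic genes, immediate early genes, glucocorticoid-responsive genes, heat shock, ribosomal proteins, Alzheimer risk genes, and neurokinin B and kisspeptin genes. Some genes belong to several lists, so calls of different lists are not independent. The pipeline was tested on simulated data with the same group sizes. It recovered 71.6 to 82.1% of genes changed 1.5-fold and 92.4 to 100% of those changed 4-fold, and made 6 to 12 false calls per comparison. It found the shifted list in each and called 0 to 2 other lists. Genes were drawn independently of each other, without a library set or a choroid plexus component, so these rates need not hold for the real libraries. Regroupings of the real libraries had a median of 9 or 10 passing lists. Replicate numbers were not used as pairs, because only 3 of 24 libraries correlated best with a library of their own number; library correlations ran from 0.971 to 0.991. Features without a symbol were tested but not named.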

Results

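RNA sequencing of the hippocampus of female rats, aged 6 months at surgery, gave 24 libraries in 4 groups. SHAM rats kept their ovaries and received vehicle (n = 7), and ovariectomised (OVX) rats received vehicle (n = 7), both for 7 weeks per the labels. Ovariectomised rats of the group called Prevention received estradiol (E2) for 5 weeks (n = 5). Those of the group called Treatment received vehicle for 3 weeks and then estradiol for 2 weeks (n = 5). The labels thus count 7 weeks of treatment for the vehicle groups and 5 weeks in all for the estradiol groups, and do not state the time between surgery and tissue collection. The deposited table held 20318 features, of which 16119 had a mean normalised count of at least 10 and were tested. Column totals ran from 35.4 to 38.8 M normalised counts (M for mega), and reads estimated from the size of the smallest steps ran from 26.5 to 53.6 M. Means below are normalised counts ± SD over the libraries of a group, changes are on the log2 scale, and positions are in the GRCr8 rat reference.

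A group of 7 libraries stood apart from the other 17. In all 5 Prevention libraries and in Treatment replicates 1 and 2, LOC257642, which is not in the reference used here, lay between 16.8 and 19.7 on the log2 scale. It lay between 14.0 and 15.2 in the other Treatment libraries and in every OVX and SHAM library. That feature, LOC500035 and a feature without a symbol together took 0.739 to 4.07% of the counts in these 7 libraries (called the high set below), against 0.0929 to 0.226% in the other 17 (the low set). Estimated reads were 39.6 to 53.6 M in the high set and 26.5 to 40.1 M in the low set. The labels name no batch, and the sets were defined after the values were seen. Because Prevention lies wholly in the high set and OVX and SHAM wholly in the low set, comparisons with Prevention had no within-set value for its vehicle controls, and a set term, estimated from the split Treatment group, stands beside them. Libraries also differed in carry-over of choroid plexus, the cerebrospinal fluid-producing tissue beside the hippocampus: Ttr, its thyroxine carrier, ran from 281 to 136652 normalised counts, with high and low libraries in every group.

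**Figure D1:**
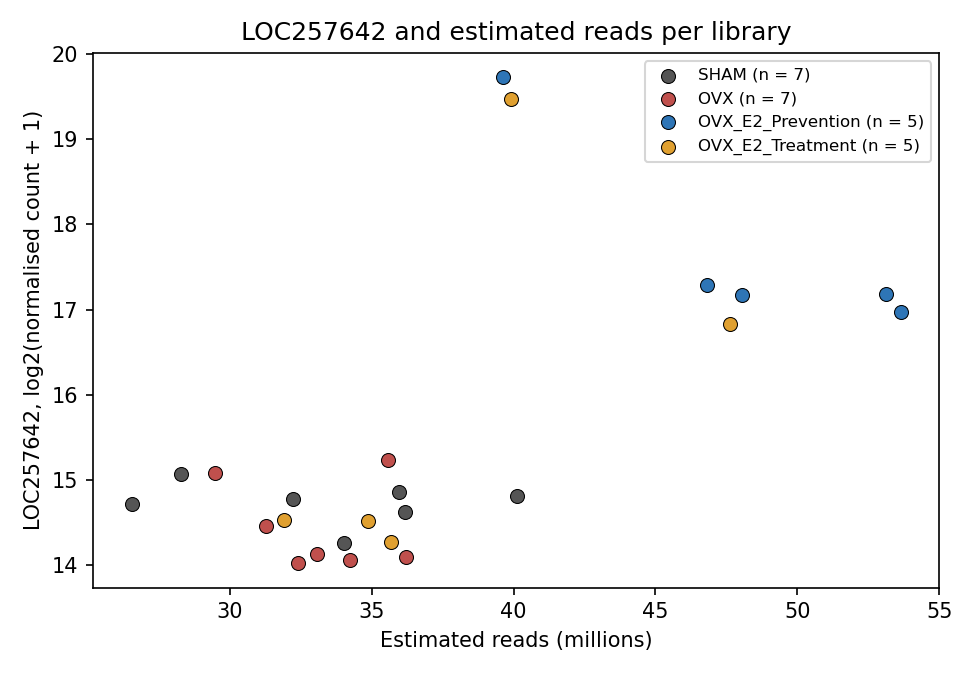
LOC257642 on the log2 scale (vertical axis) against estimated reads in M (horizontal axis) in the 24 libraries, each point a library coloured by group. All 5 Prevention libraries and 2 of 5 Treatment libraries lie between 16.8 and 19.7, and every other library lies between 14.0 and 15.2.

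The comparison of OVX with SHAM asked what loss of the ovaries changed in the hippocampus (7 against 7 libraries, all in the low set). Interferon-induced genes were higher as a group after ovariectomy: 33 of 34 tested members had a positive change, with a mean of 0.23. The call did not hold with an estimated correlation (adjusted p = 0.427), and the score per library gave an exact permutation p = 0.0659. Irf7, a transcription factor of the interferon response, measured 276 ± 84.1 against 189.9 ± 72.4 normalised counts (0.55), and the antiviral GTPase gene Mx1 205 ± 56.8 against 132 ± 37.9 (0.63). Markers of microglia, the resident immune cells of the brain, were higher in 20 of 23 (mean 0.12), among them Fcer1g, 486 ± 48.6 against 414 ± 57.8, and Trem2, 435 ± 59.6 against 376 ± 56.7. Complement genes were higher in 17 of 19 (mean 0.15), with C4a at 2036 ± 312 against 1550.5 ± 429. None of the genes named here passed on its own.

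These groups passed camera at the preset correlation, and none of the 8 lists given here did with an estimated one: interferon response (adjusted p = 6.53e-09), microglia (2.04e-06) and complement (0.000113). Cytosolic ribosomal proteins were also higher (50 of 52, mean 0.10, adjusted p = 1.06e-15), as were nuclear genes of oxidative phosphorylation (55 of 56, mean 0.05, 2.92e-07) and genes of fatty acid oxidation (15 of 24, mean 0.06, 0.0148). Genes of the glutamatergic synapse were lower (29 of 32, mean -0.13, adjusted p = 1.17e-08), among them the NMDA receptor subunit Grin2a, 3344 ± 1166 against 4604 ± 789, and the scaffold Shank1, 30049 ± 2805 against 35986 ± 4934. Markers of dentate gyrus granule cells were lower as well (10 of 12, mean -0.16, 0.00788), with Dgkh, a diacylglycerol kinase, at 525 ± 295 against 874 ± 223. These were 8 of the 34 lists tested. Each call was lost with an estimated correlation: adjusted p = 0.427 with an estimated correlation for the interferon, ribosomal, glutamatergic, microglial and complement lists, 0.593 for dentate gyrus and fatty acid oxidation, and 0.764 for oxidative phosphorylation. Adjusted over the list alone, Dgkh was the single member of these 8 lists to pass, as lower.

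Gene by gene, limma called 0 of 16119 genes between OVX and SHAM (smallest adjusted p = 0.795), while 1007 had an unadjusted p under 0.05 where 806 are expected by chance. The same 806 are expected for each such count below. The smallest p belonged to Grxcr1, known from sensory hair cells, at 132 ± 21.0 against 84.1 ± 18.4 (change 0.66, SE 0.14, adjusted p = 0.795), which did not pass. Nenf, a secreted neurotrophic factor, measured 812 ± 98.9 against 664 ± 41.1 (adjusted p = 0.795) and Wipf2, an actin regulator, 1375 ± 96.4 against 1565 ± 71.2 (adjusted p = 0.795). In simulated data with the same group sizes, but without the library set or carry-over of tissue, 71.6% of genes changed 1.5-fold were recovered. There 197 genes passed in all, which makes the adjusted threshold easier to reach. The rate therefore does not show what could be detected where few genes change.

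Prevention against OVX asked what 5 weeks of estradiol changed after ovariectomy (5 against 7 libraries). Among genes of cholesterol synthesis, Insig1, which holds back activation of the pathway, rose to 3535 ± 482 against 2727 ± 274 (change 0.37, SE 0.08, adjusted p = 0.0404), and Fdft1, squalene synthase, rose to 3563 ± 255 against 3126 ± 124 (0.19, SE 0.04, adjusted p = 0.0481). Of genes with immune functions, Cd68, a lysosomal protein of microglia and macrophages, fell to 45.1 ± 7.91 against 70.8 ± 7.54 (-0.65, adjusted p = 0.0404), the MHC class I gene RT1-T24-4 to 679.8 ± 15.0 against 1008 ± 139.5 (-0.55, adjusted p = 0.0175), and the galectin gene Lgals9 to 479 ± 28.6 against 685 ± 84.2 (-0.51, adjusted p = 0.0248). The microglia list, which holds Cd68, did not pass (mean -0.08, adjusted p = 0.0624). Grn, which encodes progranulin, fell to 1936 ± 98.2 against 2303 ± 69.1 (-0.25, adjusted p = 0.0393). The kinase gene Sik1, a target of CREB, rose to 2426 ± 762 against 1054 ± 288 (1.19, adjusted p = 0.0175).

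In all, limma called 49 genes, 32 higher and 17 lower in Prevention, and 3006 had an unadjusted p under 0.05. LOC257642 (3.23) and LOC500035 (3.12), whose level sets the high libraries apart, had the largest rises among called genes with a symbol. Next came Rdm1, a gene of DNA recombination (chromosome 10, 87062322 to 87073273), at 1227 ± 123 against 386 ± 32.0 (1.66), and Sik1 (chromosome 20, 9947104 to 9958729). Ubn2, Purb, Trnp1 and Fn1, the last encoding fibronectin, rose by 0.53, 0.50, 0.48 and 0.48. Besides RT1-T24-4 (chromosome 20, 2689329 to 2749848), Cd68, Lgals9 and Grn, falls included LOC103689945 (-0.85), Traf3ip3 (-0.48), Bola1 (-0.46), Pagr1 (-0.36) and S100a1 (-0.36).

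The called genes moved with the library set. With the set as a term limma called 0 genes (smallest adjusted p = 0.999), and 573 had an unadjusted p under 0.05 where 806 are expected by chance. The median standard error went from 0.0873 to 0.160. Over the 49 called genes the median change in the called direction went from 0.345 to 0.161. Of these genes 44 kept their sign, 11 of them with an unadjusted p under 0.05. With the term the change of Rdm1 was 0.02 and that of Sik1 0.20, and LOC257642 (-0.49), LOC500035 (-0.66) and S100a1 (0.0250) reversed. Insig1 (0.41), Fdft1 (0.26), RT1-T24-4 (-0.61), Traf3ip3 (-0.61), Pagr1 (-0.37) and Cd68 (-0.55) had changes near or above their size without the term. The count moved by over 1.5 times without any 1 of 15 libraries, from 1 without Prevention replicate 3 to 481 without OVX replicate 7.

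Among lists, cholesterol synthesis and transport was higher (17 of 25, mean 0.09, adjusted p = 0.00113), with 2 members called, 8 higher and 1 lower adjusted over the list alone, and adjusted p = 0.749 with an estimated correlation. The list's mean with the set term was 0.11 (adjusted p = 0.000386, 0.689 with an estimated correlation). The interferon list was lower in 30 of 34 (mean -0.29, adjusted p = 1.69e-06, 0.749 with an estimated correlation), with 5 lower adjusted over the list alone and none called over all genes. Irf7 measured 141 ± 13.6 against 276 ± 84.1 (adjusted p = 0.0622). With the set term the interferon mean was -0.22 (adjusted p = 0.000712, 0.689 with an estimated correlation). Complement was lower (15 of 19, mean -0.17, adjusted p = 0.00315, 0.749 with an estimated correlation), with C4a at 1421 ± 261 against 2036 ± 312, and so was MHC class I presentation (14 of 20, mean -0.10, 0.0227, 0.749 with an estimated correlation). With the set term neither passed (0.240 and 0.205).

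Glutamatergic synapse genes were higher (28 of 32, mean 0.16, adjusted p = 5.50e-05, 0.785 with an estimated correlation), Grin2b measuring 3791 ± 1158 against 2269 ± 418, and so were immediate early genes of neuronal activity (19 of 27, mean 0.19, 0.00375, 0.785 with an estimated correlation). With the set term their means were 0.03 and -0.06, and neither passed (0.498 and 0.451). Ribosomal proteins (49 of 52, mean -0.11, adjusted p = 2.91e-11, 0.753 with an estimated correlation) and oxidative phosphorylation (49 of 56, mean -0.08, 1.99e-06, 0.785 with an estimated correlation) were lower. Both had the opposite sign with the set term (0.07 and 0.06). Rps24 was the single ribosomal gene called, falling to 3258 ± 104 against 4019.6 ± 337, and 12 were lower and 1 higher adjusted over the list alone.

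**Figure D2:**
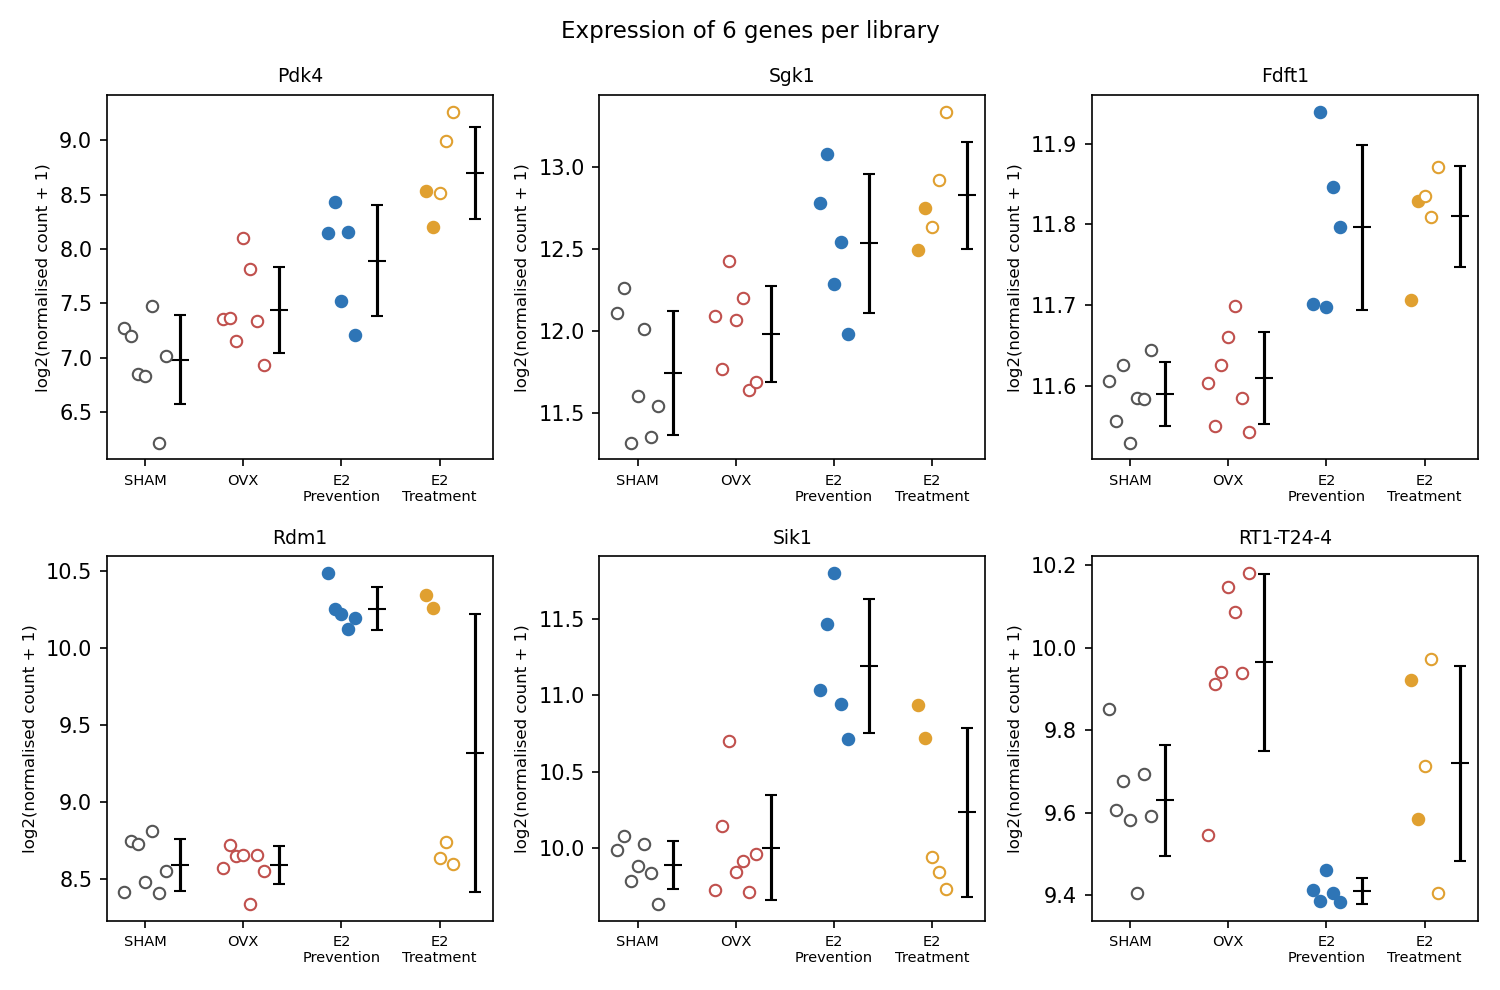
Each point is a library, with log2(normalised count + 1) of 6 genes on the vertical axis, groups on the horizontal axis, filled markers for the high set and open markers for the low set, and a bar of the mean ± SD. Rdm1 and Sik1 follow the set within the Treatment group, while Pdk4 and Sgk1 are higher in Treatment libraries of both sets than the SHAM mean.

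Treatment against OVX asked what 2 weeks of estradiol after 3 weeks of vehicle changed (5 against 7 libraries). Genes that respond to glucocorticoids were higher as a group in 19 of 20 (mean 0.30). Pdk4, a kinase that shuts off pyruvate dehydrogenase, measured 430.0 ± 129 against 178 ± 52.5 (1.26), and Sgk1, a kinase induced by serum and glucocorticoids, 7422 ± 1793 against 4119.7 ± 843 (0.84). Errfi1, a feedback inhibitor of EGF receptors, measured 1922 ± 182 against 1547 ± 130.3 (0.31), and Sult1a1, a sulfotransferase, 605 ± 29.7 against 452 ± 53.6 (0.43). Cholesterol genes were higher in 19 of 25 (mean 0.07; adjusted p = 0.879 with an estimated correlation), with Fdft1 at 3592 ± 152 against 3126 ± 124. None of these genes passed over all genes tested.

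Limma called 0 genes (smallest adjusted p = 0.258, Pdk4), and 1159 had an unadjusted p under 0.05. Within the low set, with 3 Treatment libraries, it also called 0, with 533 at an unadjusted p under 0.05; the change of Pdk4 was then 1.49 and that of Sgk1 0.98. The glucocorticoid list passed camera with the preset correlation (adjusted p = 1.27e-11) and with an estimated correlation (adjusted p = 0.00402), and 9 members were higher and 0 lower adjusted over the list alone. Within the low set its mean was 0.34 (adjusted p = 3.80e-14, 0.00627 with an estimated correlation). Its score per library, the mean log2 value of its members, was 9.97 ± 0.09 in Treatment and 9.67 ± 0.08 in OVX, with 5 of 5 Treatment libraries above every OVX library (exact two-sided permutation p = 0.00126, the smallest these sizes can give, adjusted 0.00758 over 18 such tests chosen after the values were seen).

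Cholesterol synthesis and transport passed with the preset correlation (adjusted p = 0.000121, 0.879 with an estimated correlation), with 6 members higher and 0 lower adjusted over the list alone. Within the low set its mean was 0.08 (adjusted p = 2.22e-06, 0.367 with an estimated correlation), and its score differed by 0.07 (exact permutation p = 0.0833). At the preset correlation only, immediate early genes (21 of 27, mean 0.18, adjusted p = 0.00207) and glutamatergic synapse genes (23 of 32, mean 0.10, 0.00307) were higher; the clock and activity gene Per1 measured 4147 ± 191 against 3168 ± 520.2. Myelin and oligodendrocyte genes (21 of 23, mean -0.18, adjusted p = 5.20e-05), oxidative phosphorylation (51 of 56, mean -0.05, 5.20e-05) and ribosomal proteins (47 of 52, mean -0.03, 0.000121) were lower, with Enpp6 of newly forming oligodendrocytes at 299 ± 51.0 against 397 ± 78.5. For these 5 lists the adjusted p = 0.879 with an estimated correlation, and within the low set none of them passed (smallest adjusted p = 0.301, glutamatergic synapse), with ribosomal and oxidative genes turning to means of 0.04 and 0.01. Without Treatment replicate 2, 4 lists passed instead of 7.

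**Figure D3:**
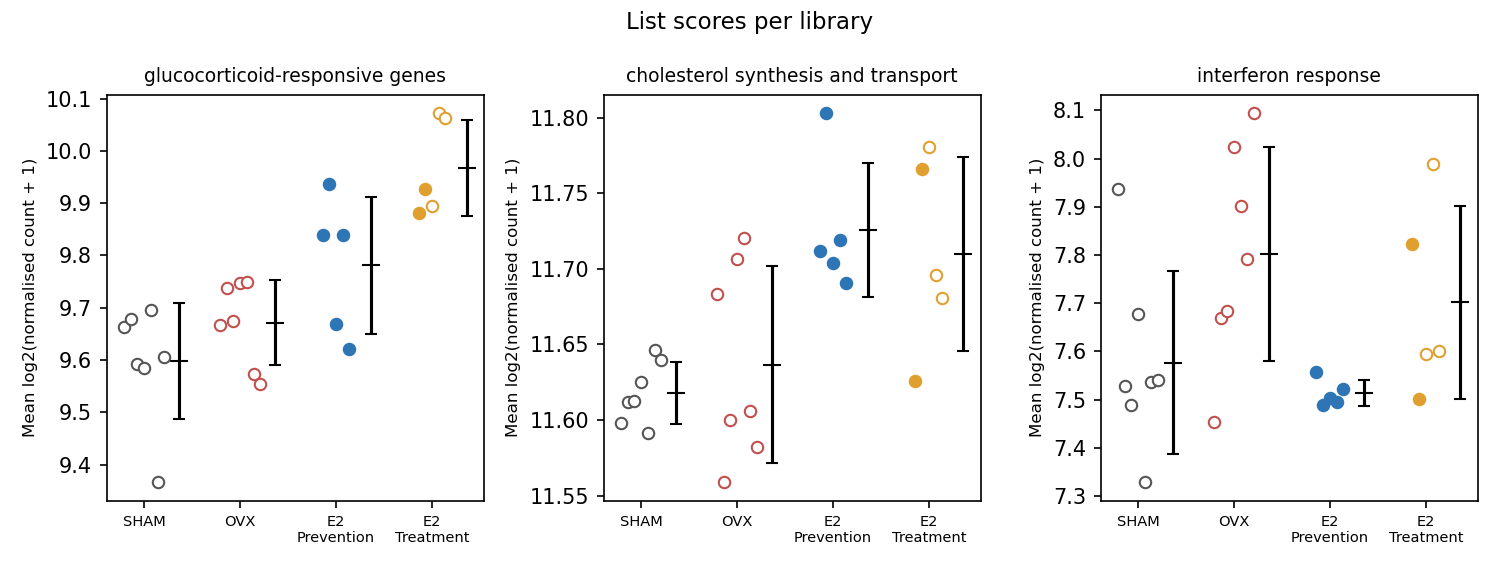
List scores, the mean log2(normalised count + 1) of the tested members of 3 lists (vertical axes), in each library by group, with filled markers for the high set, open markers for the low set, and bars of the mean ± SD. All 5 Treatment libraries lie above every OVX and SHAM library for glucocorticoid-responsive genes, with means of 9.97, 9.67 and 9.60.

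Treatment against Prevention asked whether estradiol after a period of vehicle differed from estradiol throughout treatment (5 against 5 libraries). At the preset correlation immune lists were higher in Treatment: interferon response in 30 of 34 (mean 0.19), complement in 15 of 19 (mean 0.13) and MHC class I in 15 of 20 (mean 0.15). None of these passed with an estimated correlation (adjusted p = 0.785, 0.748 and 0.748), and within the high set complement and MHC class I did not pass at the preset one (0.0683 and 0.166). Dhx58, a cytoplasmic RNA sensor, measured 169 ± 31.9 against 121 ± 10.1, Cfb, complement factor B, 338 ± 63.2 against 249 ± 26.6, and RT1-T24-4 852 ± 137 against 679.8 ± 15.0. Glucocorticoid-responsive genes were higher in 15 of 20 (mean 0.19; adjusted p = 0.138 with an estimated correlation), with the metallothionein Mt1 at 204 ± 44.4 against 137 ± 12.5 and the lipid droplet gene Plin4 at 364 ± 54.8 against 272 ± 33.6. Trnp1 measured 903 ± 147 against 1369.6 ± 213 and the homeobox gene Nkx2-4 22.1 ± 7.24 against 56.8 ± 15.6, each with adjusted p = 0.0510, just over the threshold.

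Limma called 0 genes between the estradiol groups, and 868 had an unadjusted p under 0.05; without Treatment replicate 2 it called 11, without Treatment replicate 1 it called 8 and without OVX replicate 7 it called 2. Within the high set, with 2 Treatment libraries, it called 0, with 792 at an unadjusted p under 0.05. Of 34 lists 12 passed, 9 higher and 3 lower, and none passed with an estimated correlation. Interferon (adjusted p = 8.47e-06), complement (0.00132), MHC class I (0.0184) and glucocorticoid-responsive genes (8.47e-06) were among them, and within the high set interferon (0.000416, 0.827 with an estimated correlation) and glucocorticoid-responsive genes (0.00216, 0.827 with an estimated correlation) passed at the preset correlation only. There the interferon score was 7.82 in Treatment replicate 1 but 7.50 in replicate 2, within the Prevention range of 7.49 to 7.56, so this call rests on 1 library. Both glucocorticoid scores, 9.88 and 9.93, lay within the Prevention range of 9.62 to 9.94. Adjusted over the list alone, 4 glucocorticoid-responsive genes were higher and no member of the other 11 lists passed.

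The remaining higher lists were ribosomal proteins (mean 0.08, adjusted p = 3.30e-06), oxidative phosphorylation (0.03, 0.0472), fatty acid oxidation (0.06, 0.0191), heat shock and unfolded protein response (0.06, 0.0165) and fibroblasts and extracellular matrix (0.26, 0.0330). Adjusted p = 0.785 with an estimated correlation for each of these except oxidative phosphorylation (0.841), and within the high set the ribosomal, oxidative and fatty acid means were -0.03, -0.06 and -0.01. Lower lists were glutamatergic synapse (mean -0.06, adjusted p = 0.0330), myelin and oligodendrocytes (-0.14, 0.00352) and choroid plexus and ependyma (-1.13, 0.0181), each with adjusted p = 0.830 with an estimated correlation. With the choroid score as a covariate the myelin list had a mean of -0.07 and did not pass (adjusted p = 0.142), while the fibroblast list had a mean of 0.46 (adjusted p = 3.79e-08, 0.0974 with an estimated correlation).

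Prevention against SHAM asked whether rats given 5 weeks of estradiol differed from intact rats (5 against 7 libraries). Cholesterol genes were higher in 20 of 25 (mean 0.11; adjusted p = 0.596 with an estimated correlation): Insig1 rose to 3535 ± 482 against 2666 ± 240.3 (0.40, adjusted p = 0.0259), Fdft1 to 3563 ± 255 against 3083 ± 84.1 (0.21, 0.0272) and Idi1, isopentenyl diphosphate isomerase, to 1137 ± 129 against 908 ± 36.1 (0.32, 0.0297). Sik1 rose to 2426 ± 762 against 955 ± 100.5 (1.30, adjusted p = 0.00519) and Jund, an AP-1 transcription factor, to 5556 ± 472 against 4509.9 ± 306 (0.30, 0.0384). Cebpb, a transcription factor of inflammation and metabolism, rose to 1007 ± 124 against 650.4 ± 86.9 (0.63, adjusted p = 0.0274), and Dok7, an adaptor known from neuromuscular junctions, fell to 191 ± 6.32 against 271 ± 28.7 (-0.49, 0.0130).

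Limma called 57 genes, 44 higher and 13 lower, and 2139 had an unadjusted p under 0.05. Among called genes with a symbol and a mean of at least 50, the protocadherin gene Pcdh10 had the largest rise, to 130295 ± 39842 against 17165 ± 7856 (2.98). LOC257642 (2.93), LOC500035 (2.88) and Rdm1 (1.66) followed. Mip, a lens aquaporin, rose to 1122 ± 328 against 540.0 ± 58.9 (1.01), and the ribosomal gene Rps21 to 1463 ± 46.8 against 1096 ± 113 (0.42). Falls included LOC103689945 (-0.87), Zfyve19 (-0.39) and Pagr1 (-0.28). Of the called genes, 20 were also called against OVX, all with the same sign (14 higher and 6 lower). The comparisons share the Prevention libraries, so this overlap is not independent evidence.

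With the set as a term limma called 0 genes, with 774 at an unadjusted p under 0.05, and the change of Pcdh10 became -0.05, of Sik1 0.31, of Cebpb 0.16, of Insig1 0.44, of Fdft1 0.28 and of Dok7 -0.41. Leaving out any 1 of 12 libraries moved the count by over 1.5 times, from 10 without Prevention replicate 2 to 153 without SHAM replicate 5. The cholesterol list passed (adjusted p = 1.09e-05, 0.596 with an estimated correlation), with 3 members called and 10 higher and 1 lower adjusted over the list alone. With the set term its mean was 0.13 (adjusted p = 2.67e-05, 0.687 with an estimated correlation). Its score was 11.73 ± 0.04 against 11.62 ± 0.02, higher in 5 of 5 Prevention libraries than in every SHAM library (exact permutation p = 0.00126, the smallest possible, adjusted 0.00758). Immediate early genes were higher (23 of 27, mean 0.27, adjusted p = 2.52e-05, 0.855 with an estimated correlation), with 2 called and 6 higher adjusted over the list alone, and had a mean of 0.02 with the set term. Glucocorticoid-responsive genes were higher (15 of 20, mean 0.18, 0.00638, 0.596 with an estimated correlation), with 5 higher adjusted over the list alone, Sgk1 at 6139 ± 1789 against 3531 ± 942 (adjusted p = 0.0624), and a mean of 0.29 with the set term (0.00840, 0.687 with an estimated correlation). Lower lists were heat shock and unfolded protein response (18 of 22, mean -0.08, 0.0185, 0.901 with an estimated correlation), with 1 higher and 1 lower adjusted over the list alone, and MHC class II presentation (8 of 11, mean -0.37, 0.0382, 0.855 with an estimated correlation), with 2 lower. Cd74, the MHC class II invariant chain, measured 626 ± 141 against 1006 ± 339 and had a change of 0.04 with the set term, against -0.64 without it.

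Treatment against SHAM asked whether estradiol after a period of vehicle left a difference from intact rats (5 against 7 libraries). Pdk4 (chromosome 4, 34558327 to 34568329) rose to 430.0 ± 129 against 129 ± 33.7 (change 1.72, SE 0.23, adjusted p = 0.00238). Genes of the glucocorticoid-responsive list were higher in 17 of 20 (mean 0.37), among them Sgk1 at 7422 ± 1793 against 3531 ± 942 (1.08), Ddit4, an inhibitor of mTORC1 signalling, at 3657 ± 208 against 2369 ± 310.0 (0.64), and Per1 at 4147 ± 191 against 2794 ± 228 (0.57). Nfkbia, the inhibitor of NF-kB, measured 1255 ± 230.1 against 740.2 ± 146 (0.76), and Tiparp, an ADP-ribosyltransferase, 423 ± 21.7 against 300.4 ± 14.6 (0.49). Of these only Pdk4 passed over all genes; Sgk1 had adjusted p = 0.0637.

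Limma called 1 gene, Pdk4, and 983 had an unadjusted p under 0.05. With the replicate number as a block it called 0. Within the low set it called 1, again Pdk4 (change 1.94, adjusted p = 0.00715), with 813 at an unadjusted p under 0.05. The glucocorticoid list passed with the preset (adjusted p = 3.93e-16) and the estimated correlation (adjusted p = 0.000579), 10 members being higher and 0 lower adjusted over the list alone, and within the low set its mean was 0.41 (adjusted p = 1.64e-14, 0.00556 with an estimated correlation). Its score was higher in 5 of 5 Treatment libraries than in every SHAM library (9.97 ± 0.09 against 9.60 ± 0.11, exact permutation p = 0.00126, the smallest possible). Cholesterol genes were higher (19 of 25, mean 0.09, adjusted p = 2.34e-07, 0.239 with an estimated correlation), 8 of them and none lower adjusted over the list alone, with Fdft1 at 3592 ± 152 against 3083 ± 84.1. Within the low set the cholesterol mean was 0.10 (adjusted p = 5.14e-08, 0.146 with an estimated correlation), and the score differed by 0.09 (exact permutation p = 0.00379, adjusted 0.0170), 4 of 5 Treatment libraries lying above every SHAM library.

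Other higher lists were immediate early genes (mean 0.26, adjusted p = 3.16e-06, 0.569 with an estimated correlation), with 4 higher adjusted over the list alone, and fatty acid oxidation (0.12, 0.00226, 0.569 with an estimated correlation), with 3. Per1 is also an immediate early list member and Pdk4 a fatty acid list member, while both belong to the glucocorticoid-responsive list. These calls are thus not independent of that list. The interferon list (0.12, 0.00274, 0.789 with an estimated correlation), ribosomal proteins (0.07, 0.00583, 0.975 with an estimated correlation), complement (0.11, 0.0115, 0.588 with an estimated correlation) and NF-kB and inflammatory cytokines (0.10, 0.0487, 0.569 with an estimated correlation) were higher too. In the last of these lists 1 member passed, as higher, over the list alone. Nfkbia and Lcn2 belong both to that list and to the glucocorticoid-responsive list. Within the low set the cytokine list did not pass (adjusted p = 0.0805). Myelin and oligodendrocyte genes were lower in 23 of 23 (mean -0.21, adjusted p = 2.34e-07, 0.772 with an estimated correlation), and within the low set their mean was -0.05 (adjusted p = 0.287). Without Treatment replicate 5, and likewise without Treatment replicate 6, 5 lists passed instead of 9. The gene count was 2 without SHAM replicate 1 or 2, 3 without SHAM replicate 5, 5 without Prevention replicate 2, and 4 without Prevention replicate 5 or Treatment replicate 1.

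Fold changes over the 16119 genes were compared to ask whether both estradiol schedules moved genes alike. Prevention against OVX and Treatment against OVX correlated across genes with Pearson r = 0.511 and Spearman rho = 0.579. Genes are not independent replicates, and both comparisons share the OVX libraries: 200 simulations with unchanged groups gave a mean r of 0.403 (95% of values from 0.0197 to 0.701), and 35 divisions of the OVX libraries between the comparisons gave a mean of 0.0921 (-0.144 to 0.190). The changes of OVX against SHAM and of Prevention against OVX had r = -0.409 (rho = -0.431; simulated mean -0.439; 0.00988 with OVX divided). Those of OVX against SHAM and of Treatment against OVX had r = -0.451 (rho = -0.439; simulated mean -0.427; 0.0461 with OVX divided). Each of the 3 values lay within the range of 95% of its simulations.

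No estrogen receptor gene passed in any comparison: Esr1 averaged 85.1 ± 19.3 in SHAM, 98.1 ± 32.9 in OVX, 97.3 ± 45.4 in Prevention and 84.9 ± 38.9 in Treatment, and the smallest adjusted p of Esr1, Esr2, Gper1 and Pgr over the 6 comparisons was 0.223. The astrocyte filament gene Gfap ranged between group means of 36014 and 41327, the microglial gene Aif1 between 396 and 412, C3 between 1389 and 1815, and the neurotrophin gene Bdnf between 1074 and 1302; none passed in any comparison. Lists that passed in none of the 6 comparisons, with their smallest adjusted p, were estrogen receptors and steroid enzymes (0.402), estrogen-responsive genes (0.247), neurokinin B, kisspeptin and thermoregulation genes (0.553), Alzheimer risk genes (0.212), glycolysis (0.126) and mitochondrially encoded transcripts (0.0907). The same held for markers of astrocytes (0.0540), oligodendrocyte precursors (0.0956), endothelial cells (0.252), mural cells (0.445), blood (0.0956), T cells and other leukocytes (0.0907), GABAergic neurons (0.135), CA1 (0.520) and CA2 and CA3 pyramidal cells (0.0557), and neighbouring brain regions (0.163).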

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

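Tests in this part were chosen only after the result they bear on was seen, with these exceptions. The regroupings of libraries for the interferon list were fixed before their result. The main gene and list tests were fixed in advance. So were the alternatives with the choroid score covariate, with an estimated correlation and without each library. The first pattern was the 49 genes that differed between Prevention and OVX. Of 100 regroupings of these libraries, the real one included, 2 gave a count at least as large (49 genes, highest other 894). That share is not adjusted over the 6 comparisons, and the regroupings mix the library sets. Chance is thus argued against for this count but not excluded. The highest split sets OVX replicates 1, 2, 3, 5 and 6 against the 5 Prevention libraries with OVX replicates 4 and 7. It holds part of the real contrast, and its count points to a structure of the samples that was not tested apart from it. The real contrast gave 168 genes without OVX replicate 4, 481 without OVX replicate 7 and 1 without Prevention replicate 3. Of the called genes, 93.9% had a mean of at least 100 normalised counts, so few lie near the floor. This cannot decide on lower depth of OVX libraries, as the share over all tested genes is not set beside it. Depth also goes with the library set. The share of counts taken by 3 features is argued against as the cause, since it can shift every other gene by at most 0.0599 on the log2 scale. A candidate explanation is the library set. Between the 2 high-set and 3 low-set Treatment libraries, all given the same hormone schedule, 42 of the 49 genes differed in the same direction, by a median of 0.533 of their change. In the other 9 splits at most 33 did, and of all genes 64.1% did. The 49 include LOC257642, which defines the sets and so was bound to differ, and LOC500035, which follows it. Carry-over also goes with this split: choroid scores were 5.84 and 5.67 in Treatment replicates 1 and 2, against 8.26, 10.28 and 6.40 in replicates 5, 6 and 7. Estradiol stays open and cannot be told apart from the set, since Prevention lies wholly in 1 set and limma called 0 genes with the set as a term (573 at an unadjusted p under 0.05), where Rdm1 went from 1.66 to 0.02 but Insig1 from 0.37 to 0.41, with larger standard errors (medians of 0.0873 and 0.160).

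The second pattern was the rise of glucocorticoid-responsive and cholesterol genes as groups in Treatment. Against OVX both lists kept their size within the low set and with the choroid score. For glucocorticoid genes this argues against the library set and dissection with choroid plexus as the whole cause. The score of glucocorticoid genes differed by 0.30 (SE 0.06) in all libraries, 0.34 (SE 0.07) within the low set and 0.30 (SE 0.06) with the choroid score as a covariate. That of cholesterol genes differed by 0.07, 0.08 and 0.07 (SE 0.03 each), or 2.45, 2.44 and 2.30 SE. These SE pool the spread of all groups in the fit, and SHAM had an SD of 0.02 against 0.06 in Treatment and in OVX. As the exact permutation p of the cholesterol score was 0.0833, these values cannot decide on either explanation for cholesterol genes. Camera at the preset correlation tests the genes, not this difference between scores. Within the low set and with the choroid score it gave adjusted p = 3.80e-14 and 5.87e-11 for glucocorticoid genes. For cholesterol genes it gave 2.22e-06 and 0.000491, while the exact permutation p of their score in all libraries was 0.0833. The cholesterol call was lost with an estimated correlation with and without these corrections (0.367 and 0.758; 0.879). Estradiol stays open. With the set term the mean change in Prevention against OVX was 0.21 for glucocorticoid genes and 0.11 for cholesterol genes. Without the term their scores differed by 0.11 (exact permutation p = 0.114, adjusted 0.170) and 0.09 (0.0278, adjusted 0.0714), and the glucocorticoid list did not pass. Time since surgery, handling and corticosterone levels, none of which the labels state, may act on the same genes. Permutation of libraries between groups argues against chance for the glucocorticoid list against OVX (camera p = 3.75e-13, smallest other 7.04e-12) and SHAM (1.15e-17, smallest other 2.70e-12), each 1 of 100 splits. It does so for cholesterol against SHAM in Prevention (3.22e-07, smallest other 1.24e-06, 1 split) and Treatment (1.91e-08, smallest other 1.47e-08, 2 splits). It does not for cholesterol against OVX in Prevention (0.000166, smallest other 9.46e-09, 16 splits) or Treatment (1.78e-05, smallest other 4.19e-12, 11 splits). These lists were picked from 34 after their values were seen and the shares are not adjusted for this, so chance is not excluded.

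The third pattern was the interferon list, higher in OVX than in SHAM and lower in Prevention than in OVX. A drift between ribosomal and synaptic transcripts was examined in OVX against SHAM. With that balance as a covariate the list passed at the preset correlation (adjusted p = 5.34e-10) and its score differed by 0.27 (SE 0.12), against 0.23 (SE 0.10) without it. With an estimated correlation the list passed in neither case (0.621 and 0.427). These SE pool all groups, and Prevention had an SD of 0.03 against 0.22 in OVX and 0.19 in SHAM. As the exact permutation p without the covariate was 0.0659, these values cannot decide on the drift. Ovariectomy stays open, as the score per library gave an exact permutation p = 0.0659, and so does the library set in Prevention against OVX, where the change with the set term was -0.22 (SE 0.20; adjusted p = 0.000712 at the preset correlation, 0.689 with an estimated one), against -0.29 (SE 0.11) without it. Chance was not excluded by permutation of libraries in either comparison (camera p = 3.84e-10, smallest other 3.65e-21, 8 of 100 splits, and 9.94e-08, smallest other 7.61e-22, 11 splits). In Prevention against OVX the score per library gave an exact two-sided permutation p = 0.0215, adjusted 0.0644 over 18 tests. The lower interferon score in Prevention may thus reflect an effect of estradiol, of the library set, or of chance.

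Among the other counts, 3 of 100 regroupings were as large for the 57 genes of Prevention against SHAM. The highest other gave 135, with Prevention replicates 1, 2 and 4 and SHAM replicates 2 and 5 on 1 side. This argues against chance, unadjusted over the 6 comparisons, but does not exclude it. For the 1 gene of Treatment against SHAM, 7 of 100 were as large (highest other 4), so chance was not excluded. The counts of 0 genes in OVX against SHAM, Treatment against OVX and Treatment against Prevention (highest others 2, 2 and 3; 100 of 100 each) exclude nothing; limma gave 1007, 1159 and 868 genes at an unadjusted p under 0.05. For list counts at the preset correlation chance was not excluded in any comparison: OVX against SHAM had 8 (highest other 19, 79 splits as large), Prevention against OVX 8 (17, 61 splits), Treatment against OVX 7 (20, 78 splits), Treatment against Prevention 12 (17, 29 splits), Prevention against SHAM 5 (17, 94 splits) and Treatment against SHAM 9 (19, 69 splits). The estradiol groups were compared directly: 12 lists passed at the preset correlation and 0 with an estimated one.

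Single libraries far from the rest of their group were sought with Dixon's ratio in 316 groups of values, of which 23 exceeded its critical value, where chance gives about 1 in 20, or 16. Prevention replicate 3 stood apart in 5: the share of the 3 features (4.07% against 0.800 to 1.05% in the others), LOC257642 (19.73 against 16.98 to 17.28), LOC500035 (16.07 against 13.35 to 13.73), Grin2b (12.51 against 11.64 to 11.77) and Dgkh (10.25 against 9.44 to 9.67), all on the log2 scale but the share. Treatment replicate 1 also had a high share of the 3 features (3.96% against 0.110 to 0.739%). Treatment replicate 6 stood high in Oxt (11.21 against 4.63 to 6.26), Avp (9.35 against 5.12 to 6.05) and Tcf7l2 (10.62 against 8.28 to 8.56), OVX replicate 2 in Avp (11.47 against 4.44 to 6.91) and SHAM replicate 5 in Tcf7l2 (11.71 against 8.16 to 8.62), and SHAM replicate 4 stood low in Avp (3.76 against 5.45 to 6.47). The glucocorticoid score was low in SHAM replicate 6 (9.37 against 9.58 to 9.70), and the cholesterol score high in Prevention replicate 2 (11.80 against 11.69 to 11.72). Further values were Fcer1g in SHAM replicate 1 (9.06 against 8.53 to 8.74), Grin2a in SHAM replicate 5 (11.56 against 12.06 to 12.41), RT1-T24-4 in OVX replicate 1 (9.55 against 9.91 to 10.18), Shank1 (14.57 against 14.85 to 15.02) and Mip (10.004 against 8.91 to 9.29) in OVX replicate 3, and C4a in OVX replicate 7 (11.40 against 10.77 to 11.01). In Treatment, C3 was low in replicate 2 (10.12 against 10.44 to 10.56), and replicate 5 had low Gfap (14.98 against 15.15 to 15.20) and a high share of mitochondrially encoded transcripts (7.50% against 6.68 to 6.80%).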

How the results depend on the processing

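The alternatives with the library set were chosen after seeing the data and the others before; the cause of a change was not tested unless stated. Among counts of genes past the threshold, OVX against SHAM (0 genes by limma, 1007 at an unadjusted p under 0.05) and Treatment against OVX (0 genes by limma, 1159) kept 0 calls under every alternative run. For Prevention against OVX (49 genes) the count was 97 with a mean of at least 100, where fewer genes are tested, 268 with the choroid score covariate, 5 when the pair of groups was fitted alone (2 groups only), 3 with the replicate block, and 0 with the library set term and with library set and choroid terms (limma; 573 at an unadjusted p under 0.05 with the set term). For Prevention against SHAM (57 genes) it was 88 with a mean of at least 100, 127 with the choroid score covariate, 156 with 2 groups only, 424 with library weights, 4 with the replicate block, and 0 with either set alternative (774 at an unadjusted p under 0.05 with the set term). For Treatment against Prevention (0 genes) limma called 2 with a pseudocount of 8, 2 with robust eBayes and 4 with library weights. For Treatment against SHAM (1 gene) it called 3 with quantile normalization, 6 with 2 groups only, 11 with library weights, 0 with the replicate block, and 3 with library set and choroid terms.

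Leaving out 1 library at a time left the gene count at 0 for OVX against SHAM and Treatment against OVX. For Prevention against OVX it ranged from 1 to 481: without SHAM replicates 4, 5 and 6 it was 21, 85 and 14; without OVX replicates 1 to 7 it was 11, 10, 12, 168, 96, 24 and 481; without Prevention replicates 1 to 4 it was 4, 18, 1 and 13; without Treatment replicate 1 it was 180. For Prevention against SHAM it ranged from 10 to 153: without SHAM replicates 1, 3, 4, 5, 6 and 7 it was 14, 30, 19, 153, 12 and 35; without OVX replicates 2 and 3 it was 87 and 135; without Prevention replicates 1 to 4 it was 14, 10, 16 and 13. For Treatment against Prevention it ranged from 0 to 11, and for Treatment against SHAM from 1 to 5. List counts ranged from 7 to 11 (OVX against SHAM), 6 to 11 (Prevention against OVX), 4 to 7 (Prevention against SHAM), 4 without Treatment replicate 2 to 10 (Treatment against OVX), 9 to 14 (Treatment against Prevention) and 5 without Treatment replicate 5 to 12 (Treatment against SHAM).

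An estimated correlation left 0 lists in OVX against SHAM, Prevention against OVX, Prevention against SHAM and Treatment against Prevention (camera in limma), and 1 list, the glucocorticoid-responsive genes, in Treatment against OVX and against SHAM. With the library set term 4 lists passed in Treatment against OVX, 6 in Treatment against Prevention and 11 in Prevention against SHAM (9 higher and 2 lower, from 3 and 2). Prevention against OVX likewise turned to 9 higher and 2 lower, from 3 and 5, and with library set and choroid terms 13 passed in Prevention against OVX. Quantile normalisation lost glutamatergic synapse in Treatment against Prevention (adjusted p = 0.299) and cytokines in Treatment against SHAM (0.107); upper quartile rescaling lost the latter (0.0541) and MHC class II in Prevention against SHAM (0.0549). Correlations of fold changes with the OVX libraries split between the comparisons were 0.0921 (Prevention and Treatment), 0.00988 (ovariectomy and Prevention, reversed) and 0.0461 (ovariectomy and Treatment, reversed); the shared libraries that the split removes show this cause. Ovariectomy and Prevention gave -0.0732 with the library set term and -0.215 with library set and choroid terms. Without 1 library the 3 correlations ranged from 0.419 to 0.566, -0.482 to -0.333 and -0.538 to -0.371.

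Single genes that reversed did so only with the set alternatives. In Prevention against OVX the changes were -0.49 and -0.37 for LOC257642 (set term; set and choroid terms), -0.66 and -0.58 for LOC500035, 0.0250 and 0.0229 for S100a1, and with both terms -0.0303 for Rdm1 and 0.0818 for LOC103689945. In Prevention against SHAM they were -0.78 and -0.64 for LOC257642, -0.90 and -0.82 for LOC500035, -0.0496 for Pcdh10 (set term), and with both terms -0.0378 for Rdm1 and 0.0757 for LOC103689945. Of 42 passing results for genes named by the rule, all passed with a pseudocount of 0.5 and with the choroid score, 41 with a pseudocount of 8, 40 of 40 with a mean of at least 100, 38 with quantile normalisation, 38 with upper quartile rescaling, 36 with robust eBayes, 35 with no filter, 35 with library weights, 22 with 2 groups only, 5 with the replicate block and 1 with the set term; without 1 library, 721 of 1008 did. Depth limits what can be seen of Prl and other genes under the filter; 9 of 10 estradiol libraries had any Prl.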

Other observations

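All tests in this part were chosen after the values were seen, and the genes named here lie outside the rule for naming genes. Libraries differed in carry-over of neighbouring tissue. Oxytocin (Oxt) ran from 11.6 to 4955 normalised counts, at 100 or more in 9 of 24 libraries, and vasopressin (Avp) from 12.6 to 3926, at 100 or more in 5. The thalamic gene Shox2 ran from 0 to 771 (100 or more in 7), and Tcf7l2, also thalamic, from 278 to 3357. The highest Ttr was in SHAM replicate 7, Oxt in OVX replicate 2, Avp in Prevention replicate 4, Shox2 in Prevention replicate 1 and Tcf7l2 in SHAM replicate 5, and Treatment replicate 6 was the highest of its group for all 5 genes.

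Prl, the prolactin gene (chromosome 17, 38287355 to 38298234), lay under the filter but was above 0 in 9 of 10 estradiol libraries and in 4 of 14 others. Means were 10.98 ± 14.7 in Prevention, 6.32 ± 6.06 in Treatment, 0.296 ± 0.506 in OVX and 1.07 ± 2.41 in SHAM, where 1 read is worth 0.687 to 1.38. Single libraries weigh on these means: without Prevention replicate 5 the mean was 4.44, without SHAM replicate 3 it was 0.169, and without OVX replicate 1 or 7 it was 0.176 or 0.170. Exact two-sided permutation tests of log2 values gave p = 0.00126, the smallest possible, for Prevention against OVX (adjusted 0.00758 over 6 tests), 0.0189 for Treatment against OVX (0.0284), 0.00631 for Prevention against SHAM (0.0189), 0.0833 for Treatment against SHAM (0.1; 0.0121 without Treatment replicate 1 and 0.0152 without SHAM replicate 3) and 0.878 for OVX against SHAM (0.878). The low-set Treatment libraries were higher on average than the vehicle libraries (exact p = 0.0103, adjusted 0.0206), but Prl was picked because it separates these libraries, so this test leaves the library set open. A candidate explanation is that estradiol raised prolactin transcript, whether made in the brain or carried over from blood or pituitary; growth hormone (Gh1) reached at most 2.11. It stays open as well, because Prl was found among 4199 features under the filter, 3 of which separated the estradiol libraries as far, and in 0.543 of 1000 regroupings some feature did.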
